A study of Mus musculus with 4 samples.

How the data were processed

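Expression was measured with a nanoString nCounter mouse miRNA panel in 4 samples of sorted retinal cells, 1 each of P2 RPC, P8 MG, P11 MG and adult MG. Per the labels' protocols, Cre activity was induced with 75 mg/kg tamoxifen injected into the abdomen on 2 consecutive days, starting on postnatal day 0, 6 or 9 or above the age of 21 days. tdTomato-positive cells were then sorted by flow cytometry, sorts were pooled and RNA was extracted with a micro-scale miRNA column kit. Cre line, cell type, age, number of pooled retinas and assay lane all differ between P2 RPC and the glia, so their contributions cannot be separated in those comparisons. Among the glia, age, age at tamoxifen, number of pooled retinas and assay lane likewise differ together and cannot be separated.

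The deposited raw table holds whole-number barcode counts per probe, with no processing recorded per the file headers. Its 626 probes are 566 for mouse miRNAs, 33 for viral miRNAs, 4 for housekeeping mRNAs, 8 negative, 6 positive and 6 ligation controls and 3 spike-in probes. The authors also deposited a table of processed values, treated here as a score, whose steps are not given in the sources used here and were found by setting it against the raw counts. Each score equals the raw count less the mean plus 3 SD of the lane's negative controls, times 1 factor per lane, set to 1 where lower and rounded, which gave 100% of probes to within 1 unit. The factors were 1.03 for P2 RPC, 0.771 for P8 MG, 0.989 for P11 MG and 1.34 for adult MG, proportional to the inverse of the summed background-subtracted housekeeping mRNAs, of which Actb made up 76.6%, 77.6%, 80.3% and 82.0%. Of the 566 miRNA probes, 376, 457, 450 and 424 stand at 1 in that table. The software, its version and a genome build are not given in the sources used here.

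All results start from the raw counts. Each lane was scaled by the geometric mean of its positive controls and then by that of the 100 most abundant miRNA probes, with resulting factors of 0.904, 0.925, 1.08 and 1.15 in the order above. Background was the mean plus 2 SD of the 8 negative controls, whose means were 35.8, 70.5, 50.4 and 38.6 raw counts. A count at or below background was set to the threshold, and a ratio against it is given as a bound. A miRNA was called higher or lower when it was above background in the higher library, its ratio was at least 2-fold and the exact conditional binomial 95% interval of both counts excluded equality. The intervals cover counting error only and compare these libraries, not the conditions. With 1 library per group no test between groups was possible. A list's median log2 ratio was ranked among 10000 random lists of the same size, drawn from the 30 probes nearest each member in mean expression, as a description of these libraries.

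The comparisons, the thresholds, the naming rule and 23 lists were fixed before the data were examined. The rule named the let-7 members, miR-25 and miR-124, up to 12 miRNAs per direction with the largest ratio (8 for adult MG against P2 RPC) among calls with a raw count of at least 3 times background, the 10 most abundant miRNAs of each library, and list members as examples. The lists covered the let-7, miR-29, miR-30, miR-15/16, miR-181, miR-130 and miR-200 families and the miR-106b/25, miR-17/92 with miR-106a, miR-183 with miR-96 and miR-182, and Dlk1-Dio3 clusters. They also covered neuronal, Müller glia abundant, Müller glia enriched, progenitor timing, endothelial, mural and mesenchymal, microglia and white blood cell, red blood cell, stress, pluripotency, muscle and liver, and viral miRNAs. Members were matched by name, and 8 members had no probe. A probe naming more than 1 miRNA, of which there were 9, was counted once and its members cannot be told apart. miRNA genes were placed next to each other from a gene table of assembly GRCm38.p6, used only for names and for which genes neighbour each other, with no coordinates given. It matched 227 of the 242 miRNAs above background in P2 RPC or adult MG.

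Alternatives tried were other scalings (the top 50 probes, total counts, positive controls alone, housekeeping mRNAs, edgeR's TMM factors, median-of-ratios factors), other background rules, fold thresholds of 1.5 and 3, and the authors' score table. The median-of-ratios factors used only probes above background in all 4 libraries, so they are not the factors DESeq2 would give by default. Scaling on ligation controls, scaling on the summed housekeeping mRNAs, leaving out the probes numbered miR-1894 to miR-1983, and exchanging the P8 and P11 libraries were added after the data had been seen. The steps were tested on counts simulated over 566 probes, of which 200 were changed by 3-fold or 8-fold in either direction. For each comparison all 4 lanes were Poisson draws from the second-named library alone. The first-named lane's own background and any lane, ligation or scaling error were left out. The shares below therefore do not describe the real lanes. With counting noise alone, few or no false calls at 2-fold follow from the setup. In each of the 4 comparisons 100% of changed probes above background in both libraries were called at each fold, and none of the unchanged probes, of which 151 were above background for P8 MG against P2 RPC, 90 for P11 MG against P8 MG, 99 for adult MG against P11 MG and 159 for adult MG against P2 RPC. Counting also those at background in 1 library, at an 8-fold increase 84.1%, 73.7%, 67.4% and 80.0% were called in that order, and at a 3-fold increase 52.9%, 35.7%, 43.3% and 61.1%. At an 8-fold decrease the shares were 68.2%, 73.3%, 78.6% and 77.3%, and at a 3-fold decrease 53.3%, 57.1%, 62.5% and 60.0%. In the simulation the log2 ratios were off by a median of -0.17, -0.37, -0.26 and -0.18, and the source of this offset was not tested.

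Computation used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16. Viral probes entered the comparisons only as a list, and housekeeping and control probes were left out of them.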

Results

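MicroRNAs were counted in 4 pools of mouse retinal cells sorted by their tdTomato label. The first pool held postnatal day 2 (P2) retinal progenitor cells (RPCs), labelled through Sox2-driven Cre, and the others held Müller glia (MG) from day 8 (P8), day 11 (P11) and adult retinas, labelled through Rlbp-driven Cre. The title of the P11 library reads P11/12, so its age is known to within a day. Müller glia are the radial glia of the retina and arise late from the same progenitors. The pools came from 8 retinas for P2 RPC, 52 for P8 MG, 32 for P11 MG and 40 for adult MG. Each group was 1 library, so no difference below has a replicate check and no p-value is given. The panel counts single molecules by colour-coded probes after each miRNA is ligated to a tag, and the lanes held 583699 counts for P2 RPC, 576117 for P8 MG, 583673 for P11 MG and 769736 for adult MG. Of these, 482118, 470304, 484305 and 695390 counts fell on mouse miRNA probes. Above the lane's own background stood 220 of 566 miRNA probes in P2 RPC, 134 in P8 MG, 149 in P11 MG and 171 in adult MG. The background threshold was 60.7 raw counts in P2 RPC, 137 in P8 MG, 106 in P11 MG and 71.7 in adult MG, so weak miRNAs were hardest to see in the P8 MG lane. Bracketed ranges are 95% counting intervals and cover counting error only. Between lanes, the ratios of 5 spiked positive controls had an SD of 0.08 to 0.18 on the log2 scale. For 3 ligation positive controls it was 0.10 to 0.26. After scaling on positive controls, the mean log2 ratio of the ligation controls to P2 RPC was -0.43 in P8 MG and -0.60 in adult MG.

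A few miRNAs took most of the counts, and the ranking differed with age. In P2 RPC the most abundant was miR-9, a neural miRNA, with 57830 normalized counts or 13.3% of miRNA counts, followed by miR-16, miR-720, miR-204 and miR-181a. The probe shared by miR-20a and miR-20b, then miR-25, miR-15b, let-7g and let-7d filled the remaining places of its top 10. In P8 MG miR-9 was again first at 21.4%, and miR-204, which is abundant in the retinal pigment epithelium and in glia, was second at 11.9%. In P11 MG miR-204 (20.5%) and miR-9 (18.5%) changed places. In adult MG miR-204 alone made up 35.6% of miRNA counts, with miR-125b-5p second at 13.7% and miR-9 next at 9.40%. let-7c, let-7b, let-7d, let-7g, miR-16 and miR-181a were in the top 10 of P8 and P11 MG, miR-99a entered it in P11 and adult MG, and miR-30c in adult MG. The 10 most abundant probes held 56.1% of miRNA counts in P2 RPC, 63.4% in P8 MG, 71.5% in P11 MG and 79.4% in adult MG. The miR-720 probe, whose sequence was later assigned to a tRNA fragment, had 23921 normalized counts in P2 RPC and 23810 in adult MG.

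The series title names miR-25, let-7 and miR-124 in the neurogenic potential of Müller glia, so these come first; the study chose them, and where it did so on these samples their directions are not independent evidence. miR-25, a member of the miR-106b/25 cluster that is abundant in dividing progenitors, had 18539 normalized counts in P2 RPC, 6478 in P8 MG, 3522 in P11 MG and 2388 in adult MG. It was 2.86-fold lower (2.78 to 2.94) in P8 MG and 7.76-fold lower (7.42 to 8.12) in adult MG than in P2 RPC. miR-124, the classical neuronal miRNA, went from 6341 in P2 RPC to 2883 in P8 MG, 1322 in P11 MG and 1391 in adult MG, which was 2.20-fold lower (2.11 to 2.30) in P8 MG and 4.56-fold lower (4.29 to 4.85) in adult MG. In P8 MG its log2 ratio missed the 2-fold threshold when scaled on the top 50 probes (-0.94) or the ligation controls (-0.92), and was -2.16 on housekeeping mRNAs. The let-7 family, heterochronic miRNAs that accumulate as cells mature, did not move as a block. let-7c had 6354 normalized counts in P2 RPC against 26071 in adult MG, a ratio of 4.10 (3.995 to 4.215), and let-7b 6227 against 17983, a ratio of 2.89 (2.81 to 2.97) that missed the 2-fold threshold on total counts. let-7i went the other way, from 11148 to 2466, and was 4.52-fold lower (4.32 to 4.73). let-7a, let-7d, let-7e and let-7g differed little between P2 RPC and adult MG, let-7g having the largest ratio of these at 1.10, and let-7f and miR-98 had log2 ratios of -0.57 and -0.56. The median log2 ratio of the 9 members was -0.04 in P8 MG against P2 RPC and -0.08 in adult MG against P2 RPC, and the other scalings put it between -1.07 and 0.18 and between -0.95 and 0.36, so the sign of the family median depended on the scaling. The contrast between let-7b or let-7c and let-7i did not, since a scaling moves all ratios of a comparison by the same amount.

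**Figure D1:**
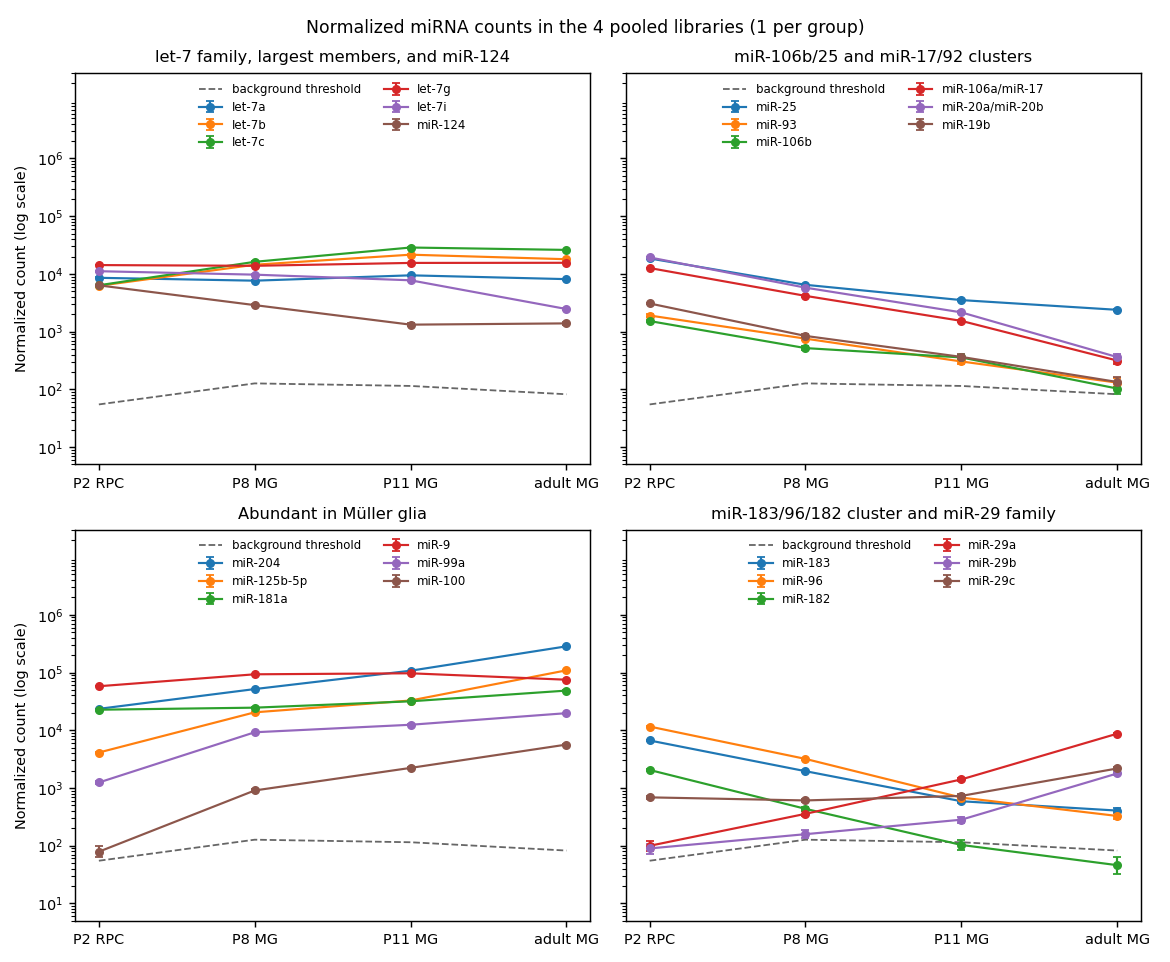
Normalized counts (log axis) of named miRNAs in the 4 libraries, 1 per group, with 95% Poisson intervals of the counts as bars and the lane's background threshold as a dashed line. miR-25 went from 18539 in P2 RPC to 2388 in adult MG and miR-204 from 23470 to 284092, while let-7a stayed between 7638 and 9458.

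The first comparison set P8 MG against P2 RPC, young glia against the progenitors they derive from. Higher in P8 MG were miR-100 by 11.5-fold (9.23 to 14.5), miR-99a by 7.42-fold (7.01 to 7.86) and miR-125b-5p by 4.97-fold (4.81 to 5.13), while the related miR-99b and miR-125a-5p had log2 ratios of -0.62 and -0.18. miR-204 was 2.20-fold higher (2.17 to 2.23), but its log2 ratio was 0.11 on housekeeping mRNAs, 0.55 on TMM factors, 0.69 on summed housekeeping mRNAs and 0.93 on positive controls, all under the threshold. Lower in P8 MG were the proliferation-associated miR-17/92 and miR-106a clusters, with miR-19a 6.36-fold lower (5.95 to 6.80), and the photoreceptor cluster of miR-183, miR-96 and miR-182, with miR-182 4.71-fold lower (4.27 to 5.22). In all, 29 miRNAs were at least 2-fold higher, 21 at least 2-fold lower and 179 of the 229 above background in either library neither. For 9 of the higher and 1 of the lower, the weak side was at background and the ratio is a bound. Besides those above, the largest measured ratios among well-counted miRNAs were miR-2141 (5.18-fold), miR-22 (4.36), miR-709 (3.44), miR-129-3p (3.37), miR-1224 (2.88), let-7c (2.55), miR-322 (2.38) and let-7b (2.32) on the higher side. The raw P8 MG to P2 RPC ratio of miR-2141 was 5.06, above the 3.50 that background probes reached, and its raw P8 MG to P11 MG ratio of 2.75 lay within their range, up to 2.77. Its raw counts of 1088 in P8 MG and 396 in P11 MG lay above all negative controls, which reached at most 114 and 97. On the lower side followed miR-301a (4.67-fold), miR-130b (3.67), miR-19b (3.65), miR-96 (3.63), miR-183 (3.40), the miR-20a and miR-20b probe (3.34), miR-15b (3.34), the miR-106a and miR-17 probe (3.04), miR-106b (2.94) and miR-374 (2.90). miR-218, a neuronal miRNA, was at least 2.13-fold lower. By list, all 3 members of the miR-106b/25 cluster were lower (median log2 ratio -1.52, lower than in all but 7.97% of random lists of like abundance), as were all 3 of the miR-183 cluster (median -1.86, percentile 4.26) and 4 of 6 of the miR-17/92 and miR-106a clusters (median -1.67, percentile 0.05). Of 8 miRNAs listed as abundant in Müller glia, 4 were higher and none lower (median 1.03, percentile 99.9, and a median of 0.0092 on housekeeping mRNAs), and miR-9, at 0.69, miR-135a, at 0.93, miR-181a, at 0.12, and miR-125a-5p, at -0.18, were neither. The housekeeping scaling weighs its 4 mRNAs equally, and B2m changed most among them, from 92 raw counts in P2 RPC to 543 in P8 MG. It moved log2 ratios by -1.03 here, against -0.45 for the summed housekeeping mRNAs. Scaled on housekeeping mRNAs the split was 8 higher and 84 lower, on edgeR's TMM factors 13 and 44, on positive controls 24 and 28, on summed housekeeping mRNAs 16 and 39, and on the top 50 probes or the ligation controls 35 and 16, and 8 of the 29 higher and 16 of the 21 lower calls held under all 8 scalings. Of the 12 higher miRNAs with ratios above, miR-100, miR-99a, miR-2141, miR-125b-5p and miR-22 held under all 8, and of the lower ones with ratios in this paragraph all but miR-218 did.

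**Figure D2:**
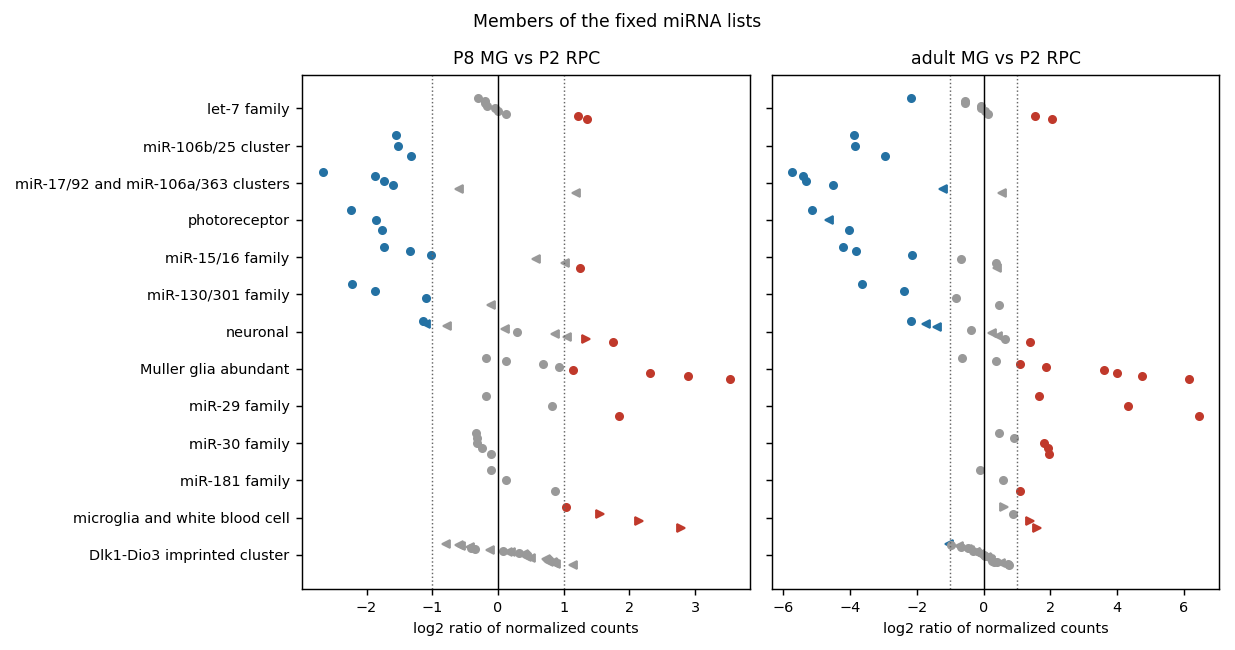
Log2 ratios of the members of 13 fixed miRNA lists in P8 MG and adult MG against P2 RPC, 1 library per group. Red marks members at least 2-fold higher, blue at least 2-fold lower and grey neither, and triangles are bounds with 1 library at background; all 3 members of the miR-106b/25 cluster are blue in both panels.

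The second comparison, P11 MG against P8 MG, covered a few days of glial age and gave the fewest differences. miR-29a, which targets collagen and other matrix transcripts and accumulates in mature cells, was 3.95-fold higher (3.52 to 4.43), followed by miR-365 (2.56-fold), miR-100 (2.46-fold) and miR-204 (2.08-fold, 2.06 to 2.10). The miR-183 cluster was again lower, miR-96 by 4.67-fold (4.29 to 5.10), miR-183 by 3.32-fold and miR-182 by at least 3.79-fold. The probe of miR-106a and miR-17 was 2.71-fold lower (2.56 to 2.88), that of miR-20a and miR-20b 2.68-fold, miR-93 2.48-fold, miR-2141 2.35-fold, miR-19b 2.31-fold, miR-19a 2.19-fold and miR-124 2.18-fold (2.04 to 2.33). These 4 higher and 10 lower miRNAs were all that passed the threshold among 157 above background in either library, and the rank correlation across probes was 0.936 (Spearman, across miRNAs, which are not replicates). miR-25 was 1.84-fold lower (1.76 to 1.92), under the threshold, and passed it on total counts (-1.15), positive controls (-1.08) and ligation controls (-1.15). Of the 9 let-7 members none passed it, let-7c having the largest ratio at 1.77-fold higher (1.73 to 1.80), with a family median of 0.26 that the total count and ligation scalings moved to -0.01. All 4 measured members of the miR-17/92 and miR-106a clusters were lower (median -1.31, percentile 0.14), all 3 of the miR-183 cluster (median -1.92, percentile 0) and 1 of 3 of the miR-106b/25 cluster (median -0.88, percentile 4.01). In the Müller glia list 2 of 8 were higher (median 0.42, percentile 98.5). Scaling on total counts or on the ligation controls changed the split to 3 higher and 15 lower, where miR-204 was lost (down to 0.79), as it was on positive controls, and miR-19a just missed the threshold on housekeeping mRNAs and miR-124 on these and on summed housekeeping mRNAs.

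The third comparison, adult MG against P11 MG, spanned the later glial ages. The miR-29 family was higher throughout, miR-29b by 6.33-fold (5.54 to 7.24), miR-29a by 6.20-fold (5.84 to 6.58) and miR-29c by 2.99-fold. miR-125b-5p was 3.33-fold higher (3.29 to 3.37), miR-30c 3.40-fold, miR-30a 3.12-fold and miR-204 2.65-fold (2.63 to 2.66). The miR-20a and miR-20b probe was 5.95-fold lower (5.28 to 6.72) and the miR-106a and miR-17 probe 4.87-fold. let-7i was 3.15-fold lower (2.997 to 3.303) and miR-98, another let-7 member, 2.05-fold lower. In all, 23 miRNAs were at least 2-fold higher, 22 at least 2-fold lower and 134 neither. miR-23a (3.90-fold), miR-365 (3.42), miR-338-3p (3.15), miR-211 (3.06) and miR-1968 (2.74) completed the higher names. miR-211 is nearly identical in sequence to miR-204 and its counts are uncertain for that reason. With a line on miR-204 drawn through P2 RPC and adult MG, raw miR-1968 counts deviated by 0.05 in P8 MG and -0.29 in P11 MG (log2). By construction P2 RPC and adult MG lie on that line. Also lower were miR-322 (5.28-fold), miR-340-5p (5.26), miR-146a (4.35), miR-106b (3.46), miR-15b (3.44), miR-15a (3.33), miR-19a (3.06), miR-19b (2.72) and miR-210 (2.47), the last known as a hypoxia-induced miRNA. Among the lists, 3 of 3 miR-29 members (median 2.63, percentile 100) and 3 of 5 miR-30 members (median 1.39, percentile 99.1) were higher. The remaining miR-30 members, miR-30b and miR-30e, passed as higher under 6 and 4 of the 8 scalings. Lower were 4 of 4 miR-17/92 and miR-106a members (median -1.95, percentile 0.04), 2 of 3 of the miR-106b/25 cluster (median -1.22, percentile 4.14), 3 of 5 of the cell-cycle-related miR-15/16 family (median -1.74, percentile 0.06) and 1 of 2 in the miR-183 cluster (median -0.80). The let-7 median was -0.26 with 2 of 9 lower, and between -0.86 and 0.23 under the other scalings. miR-25 was 1.47-fold lower (1.40 to 1.56) and miR-124 did not differ beyond counting error (1.05-fold, 0.971 to 1.14), and the other scalings put their log2 ratios between -1.16 and -0.073 and between -0.53 and 0.56, with miR-25 past the threshold on total counts. Total counts gave 9 higher and 50 lower, the ligation controls 41 and 11, housekeeping mRNAs 39 and 11 and summed housekeeping mRNAs 35 and 13. Positive controls gave 31 and 15, TMM factors 30 and 16 and the median of ratios 27 and 17. Of the miRNAs with ratios above, miR-29c, miR-204 and miR-1968 were lost on total counts, miR-19b on housekeeping mRNAs and ligation controls, miR-210 on these and on summed housekeeping mRNAs, and miR-98 under 6 of the 8 scalings. Among the list members, miR-30d was lost on total counts, miR-93 under 4 scalings and miR-96 under 6.

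The fourth comparison set mature glia against the P2 progenitors. miR-29a was 87.6-fold higher (72.6 to 107) in adult MG than in P2 RPC, miR-100 71.7-fold (58.0 to 89.7) and miR-125b-5p 26.5-fold (25.7 to 27.3), and miR-204 was 12.1-fold higher (12.0 to 12.3). The miR-20a and miR-20b probe was 53.3-fold lower (47.7 to 59.8), miR-19a 42.6-fold (35.6 to 51.5) and miR-96 35.4-fold (31.5 to 39.9). Here 50 miRNAs were at least 2-fold higher, 40 at least 2-fold lower and 152 of 242 neither, with 13 of the higher and 12 of the lower being bounds. Of the 50 higher, 13 were probes numbered miR-1894 to miR-1983, for which spill-over from the miR-204 probe is a candidate explanation given below. Other large ratios on the higher side were miR-29b (19.9-fold), miR-365 (16.5), miR-99a (15.9), miR-23a (13.8) and miR-22 (13.2), with bounds of at least 10.5-fold for miR-125b-3p, 6.89-fold for miR-211 and 5.32-fold for miR-1933-5p, which was at background in P2 RPC and P8 MG. On the lower side stood the miR-106a and miR-17 probe (40.1-fold), miR-19b (22.9), miR-15b (18.6), miR-183 (16.4) and miR-106b (14.8). miR-182 was at least 24.9-fold lower, and smaller bounds held for miR-296-5p, miR-218, miR-484, miR-138, miR-216b, miR-18a and miR-450a-5p, from 3.97-fold down to 2.26-fold. All 3 members of the miR-106b/25 cluster were lower (median -3.86, percentile 1.91), as were 5 of 6 miR-17/92 and miR-106a members (median -4.92, percentile 0) and all 3 of the miR-183 cluster (median -4.64, percentile 0.78). Of the Müller glia list 6 of 8 were higher (median 2.74, percentile 100), the exceptions being miR-9, at 0.38, and miR-125a-5p, at -0.65. The miR-29 family was higher in 3 of 3 (median 4.32, percentile 99.9) and the miR-30 family in 3 of 5 (median 1.81, percentile 96.4). In the let-7 family 2 of 9 were higher and 1 lower. Total counts gave 23 higher and 87 lower, housekeeping mRNAs 36 and 61, the top 50 probes 61 and 28 and the ligation controls 78 and 25. Under all 8 scalings 23 of the 50 higher and 25 of the 40 lower calls held, miR-138, miR-216b, miR-18a and miR-450a-5p were lost on the ligation controls, the last 2 also on the top 50 probes, and the list members miR-29c, miR-30a, let-7b and miR-181a on total counts, miR-181a (0.23 there) also on housekeeping mRNAs, TMM factors and positive controls.

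**Figure D3:**
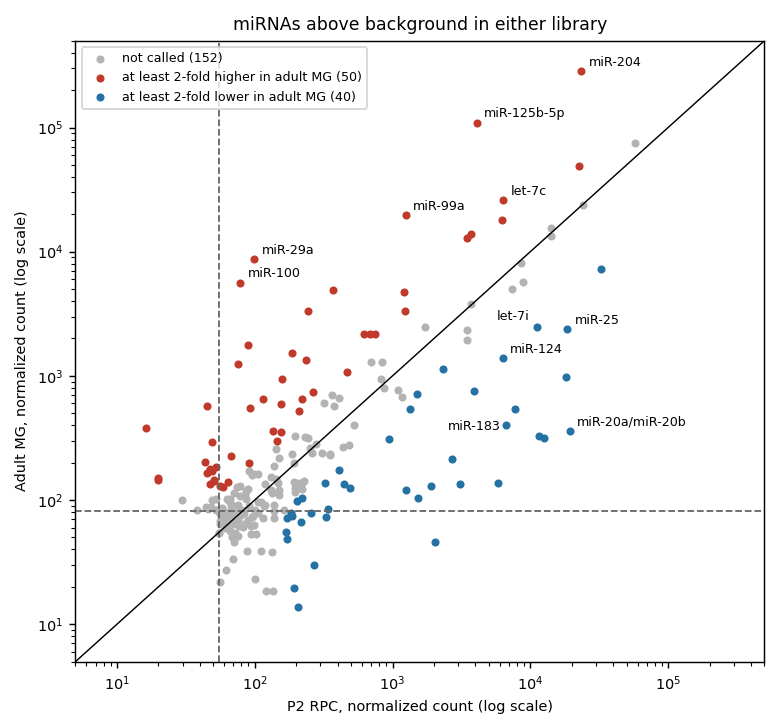
Normalized counts of the 242 miRNAs above background in either library, P2 RPC on the x axis and adult MG on the y axis (both log), with the diagonal of equal counts and each lane's background threshold dashed. Red points are the 50 miRNAs at least 2-fold higher in adult MG, led by miR-29a at 87.6-fold, and blue points the 40 at least 2-fold lower, led by the miR-20a and miR-20b probe at 53.3-fold.

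Over the 3 glial ages most of the large differences ran in age order. miR-29a had 356 normalized counts in P8 MG, 1405 in P11 MG and 8709 in adult MG, and miR-204 had 51643, 107406 and 284092. The miR-20a and miR-20b probe had 5781, 2158 and 362.8. Of 27 miRNAs at least 2-fold higher in adult MG than in P8 MG, 26 had P11 MG between them, and of 31 at least 2-fold lower, 26 did. With counts at background set to the threshold and steps within background left out, 25 and 25 did, without miR-211 and miR-182. These miRNAs were chosen for a difference between the end ages, which by itself favours a middle value between them, so no chance share is given. The exceptions were miR-720 on the higher side and miR-322, miR-146a, miR-210, miR-124 and miR-1196 on the lower side, named here because they broke the order. On total counts the ordered numbers were 15 higher and 71 lower, and on housekeeping mRNAs 51 and 16. The ordered higher miRNAs include miR-1896, miR-1900, miR-1927, miR-1933-5p, miR-1960, miR-1965, miR-1966 and miR-1968. For these, spill-over from the miR-204 probe is a candidate explanation given below. They and miR-211, nearly identical in sequence to miR-204, may therefore not be signals separate from miR-204.

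Other families on the fixed lists showed these patterns. In the miR-15/16 family, which targets cyclins, miR-15a, miR-15b and miR-16 were lower in P8 MG than in P2 RPC while miR-322 was higher (median of all 6 -0.22, of those measured in both -1.18). In adult MG against P2 RPC the same 3 were lower, miR-16 by 4.46-fold and miR-15a by 14.2-fold (median -1.42, percentile 1.28), and none of 5 passed the threshold between P8 and P11 MG (median -0.41). In P11 MG against P8 MG miR-15a did pass as lower on total counts and on ligation controls (-1.02 on each). In the miR-130 family, miR-130a, miR-130b and miR-301a were lower in P8 MG (3 of 4, median -1.48, percentile 1.41) and miR-130b and miR-301a in adult MG against P2 RPC (2 of 4, median -1.60, percentile 10.4). In the latter miR-130a, at -0.83, passed as lower under 3 of the 8 scalings. None of the family's 3 measured members passed between P8 and P11 MG (median -0.54), and miR-130b alone was lower in adult MG against P11 MG (1 of 4, median 0.37, -0.24 on total counts). There miR-301b, a bound at 0.73, passed as higher under 3 of the 8 scalings. In the miR-29 family miR-29a was higher in P8 MG than P2 RPC and in P11 MG than P8 MG (1 of 3 each, medians 0.82 and 0.83, the first -0.20 on housekeeping mRNAs). No miR-30 member passed in either early comparison (medians -0.32 and 0.39), though all 5 passed as lower in P8 MG on housekeeping mRNAs. In the miR-181 family miR-181a was 2.14-fold higher in adult MG than P2 RPC (1 of 3, median 0.59, -0.28 on total counts) and no member passed in the other comparisons, with medians of 0.12 and 0.01 before P11, both of which turned sign under other scalings, and 0.62 in adult MG against P11 MG, where miR-181a passed on housekeeping mRNAs and ligation controls. There miR-181c passed as higher on these and on summed housekeeping mRNAs, and the miR-181b and miR-181d probe as lower on total counts (-1.58). In P8 MG against P2 RPC that probe passed as higher on the top 50 probes and ligation controls, and miR-181c as lower on housekeeping mRNAs. Of the neuronal list, miR-124 and miR-218 were lower and miR-129-3p and miR-129-5p higher in P8 MG than P2 RPC (2 and 2 of 9, median 0.29, -0.73 on housekeeping mRNAs). In adult MG against P2 RPC miR-124, miR-138 and miR-218 were lower and miR-129-3p higher (3 and 1 of 8, median -0.08, 0.36 on ligation controls, and 0.12 over the 4 measured in both), miR-124 alone was lower in P11 MG against P8 MG (1 of 4, median -0.32), and none of 4 passed in adult MG against P11 MG (median 0.04, -0.56 on total counts). The progenitor timing list adds miR-9, miR-125a-5p and miR-125b-5p to 8 let-7 members also counted above. miR-125b-5p, let-7b and let-7c were its higher members in P8 MG and in adult MG against P2 RPC, let-7i its lower one in the latter, and its 4 medians, -0.04, 0.21, -0.26 and 0.05, turned sign under other scalings. Of 24 miRNAs of the imprinted Dlk1-Dio3 cluster, miR-410 alone passed in adult MG against P2 RPC (at least 2.07-fold lower), none of 24 did in P8 MG against P2 RPC and none of 9 in P11 MG against P8 MG. Other scalings added calls. In P8 MG against P2 RPC these included miR-495 as lower under 4 of 8, miR-136 and miR-376c under 3 and miR-410 under 2. In adult MG against P2 RPC they included miR-369-3p as lower under 4 and miR-376b under 3, and miR-127 and miR-154 as higher under 2. In adult MG against P11 MG 1 of 12 passed by the main rule, miR-376a as lower, while miR-136, at 0.99, passed as higher under 7 of the 8 scalings. The 4 medians, 0.40, 0.09, -0.06 and -0.05, turned sign with scaling. Most of the 24 ratios behind the first are bounds, and over members measured in both libraries the 4 medians were -0.14, -0.06, 0.05 and 0.03. The calls of this paragraph lost under at least 1 scaling were, for P8 MG against P2 RPC, miR-16, miR-322, miR-130a, miR-29a, miR-124, miR-218, miR-129-3p, miR-129-5p, let-7b and let-7c, and miR-124 for P11 MG against P8 MG. They were miR-130b and miR-376a for adult MG against P11 MG, and miR-181a, miR-138, miR-129-3p, let-7b and miR-410 for adult MG against P2 RPC.

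Markers of other cell types that a sort could carry along were also listed. The photoreceptor and neuronal lists given above hold such markers too. In P8, P11 and adult MG, miR-96 had 3186, 682 and 327 normalized counts and miR-124 2883, 1322 and 1391. Whether carried-along cells added to these counts was not tested. All 4 microglia and white blood cell miRNAs above background were higher in P8 MG than in P2 RPC, miR-146a by at least 6.86-fold, miR-142-3p by at least 4.42-fold, miR-150 by at least 2.92-fold and miR-142-5p by 2.05-fold (median 1.84, percentile 100). On housekeeping mRNAs the median was 0.82, and the call of miR-142-5p was lost under 5 of the 8 scalings and that of miR-150 under 2. Raw counts of B2m mRNA, an immune-associated housekeeping gene on the panel, were 92, 543, 629 and 375 from P2 RPC to adult MG. B2m enters the housekeeping scaling, and the other mRNAs in it changed less between P2 RPC and P8 MG. That scaling is therefore not independent of an immune-associated signal. Between P8 and P11 MG none of the 4 passed the threshold (median -0.09, 0.04 on housekeeping mRNAs), miR-146a and miR-142-3p were lower in adult MG than P11 MG (2 of 4, median -0.76), and miR-150 and miR-146a were higher in adult MG than P2 RPC (2 of 4, median 1.13). In the stress and injury list miR-146a and miR-210 were higher in P8 MG (2 of 4, median 0.97, -0.05 on housekeeping mRNAs) and lower in adult MG than P11 MG (2 of 4, median -1.02), with none of 3 passing between P8 and P11 MG (median 0.12) and miR-146a alone higher in adult MG than P2 RPC (1 of 4, median 0.28, -0.13 over those measured in both), the last 2 medians turning sign under other scalings. In the mural and mesenchymal list miR-22, which many cells express, was higher in P8 MG than P2 RPC (4.36-fold), in adult MG than P11 MG (2.27-fold) and in adult MG than P2 RPC (13.2-fold), and was 1.34-fold higher in P11 MG, under the threshold. miR-143, miR-145, miR-214 and miR-199a-5p, listed both there and as enriched in Müller glia, were at background in all libraries, which left miR-29a as the measured member of the glia-enriched list. Endothelial miR-126-3p did not pass in any comparison (log2 ratios 0.48, -0.13, -0.71 and -0.36, the others than -0.71 turning sign with scaling and the last 2 passing on total counts), nor did epithelial miR-200b (0.87, -0.13, -0.28 and 0.46, all turning sign and the first past the threshold on the top 50 probes and ligation controls). miR-200a and miR-200c were at background in all the glia, so their ratios to P2 RPC are upper bounds without a direction. Red blood cell and pluripotency miRNAs were at background in all 4 libraries. Of the muscle and liver miRNAs, miR-208a was at least 2.72-fold higher in adult MG than P2 RPC at 149 normalized counts, and no other passed. The other calls of this paragraph lost under at least 1 scaling were miR-210 in P8 MG, miR-142-3p, miR-210 and miR-22 in adult MG against P11 MG, and miR-150, miR-146a and miR-208a in adult MG against P2 RPC.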

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

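No test was run on the results in this part, and all values are raw counts. They were picked out because they are signals above background in probes other than those for mouse miRNAs. The thresholds were 60.7 counts in P2 RPC, 106 in P11 MG and 71.7 in adult MG.

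Of the 33 viral miRNA probes, 5 passed a lane's threshold, all by a small margin, and no viral probe was called higher or lower in any of the 4 comparisons. In P2 RPC, mcmv-miR-m01-2 had 64 counts, mcmv-miR-m107-1-5p 62 and mghv-miR-M1-4 63. In adult MG, mghv-miR-M1-7-5p had 91 counts, which is 1.27 times the threshold and the largest such excess, and mcmv-miR-m59-2 had 79 and passed in 2 libraries. The ligation negative control LIG_NEG_A had 65 counts in P2 RPC, 1.07 times the threshold.

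The panel's 4 housekeeping mRNAs stood above background in all 4 libraries and did not keep a fixed proportion to one another. Actb, which encodes beta-actin, had 8497 counts in P2 RPC, 11535 in P8 MG, 9301 in P11 MG and 7024 in adult MG. Gapdh, a glycolytic enzyme, had 651, 1423, 936 and 730. Rpl19, a ribosomal protein gene, had 2047 in P2 RPC, 1829, 1090 and 681. B2m, which encodes the light chain of MHC class I, had 92, 543, 629 and 375, with its highest count of 629 in P11 MG.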

How the results depend on the processing

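Scaling on the summed housekeeping mRNAs and on the ligation controls, leaving out the probes numbered miR-1894 to miR-1983, and exchanging the P8 and P11 libraries were chosen only after the result was seen. No paired analysis was possible because each group was 1 library. The 8 other scalings moved all log2 ratios of a comparison together, by -1.03 to 0.22 for P8 MG against P2 RPC, -0.27 to 0.13 for P11 MG against P8 MG, -0.60 to 0.49 for adult MG against P11 MG and -0.87 to 0.44 for adult MG against P2 RPC. List medians kept their sign under all 8 scalings for 11 of 20, 11 of 19, 13 of 20 and 11 of 20 lists in the order above, bounds included. miR-25 and miR-124 were lower in P8 MG and in adult MG than in P2 RPC under all settings run. Calls held under all 8 scalings for 8 of 29 higher and 16 of 21 lower in P8 MG against P2 RPC, 3 of 4 and 8 of 10 in P11 MG against P8 MG, 9 of 23 and 11 of 22 in adult MG against P11 MG and 23 of 50 and 25 of 40 in adult MG against P2 RPC. The authors' score table kept 16 of 29 and 21 of 21, 4 of 4 and 10 of 10, 23 of 23 and 20 of 22, and all 50 and 40. Scalings differ in counts because they shift all ratios; why the controls differ between lanes was not tested. Raw background, highest in P8 MG, limits what can be seen among weak miRNAs. No alternative was left out.

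In the values below, counts are of miRNAs at least 2-fold higher or lower, and ordered means running in age order over the 3 glial ages. Housekeeping mRNAs gave 8 higher and 84 lower in P8 MG against P2 RPC, 39 and 11 in adult MG against P11 MG, 61 lower in adult MG against P2 RPC, and 51 ordered up and 16 down. For P8 MG against P2 RPC they gave log2 ratios of -1.07 for the let-7 median, -2.54 for miR-25 and -2.16 for miR-124, and for adult MG against P2 RPC -0.50, -3.38 and -2.62. TMM factors gave 13 higher and 44 lower in P8 MG against P2 RPC and 40 ordered up, with let-7, miR-25 and miR-124 at -0.62, -2.10 and -1.72 in P8 MG and -0.35, -3.23 and -2.46 in adult MG. Summed housekeeping mRNAs gave 16 and 39 in P8 MG against P2 RPC, 35 and 13 in adult MG against P11 MG, 46 ordered up and 17 down, and -0.49, -1.96 and -1.58 in P8 MG. Total counts gave 9 and 50 in adult MG against P11 MG, 23 and 87 in adult MG against P2 RPC, 15 ordered up and 71 down, and -0.95, -3.83 and -3.06 in adult MG. Ligation controls gave 41 and 11 in adult MG against P11 MG, 78 and 25 in adult MG against P2 RPC, 0.18, -1.30 and -0.92 in P8 MG, and 0.36, -2.52 and -1.75 in adult MG. The top 50 probes gave 0.15, -1.32 and -0.94 in P8 MG and 0.19, -2.69 and -1.93 in adult MG, so that miR-124 missed the 2-fold threshold in P8 MG under these last 2 scalings. Positive controls alone gave -0.25, -1.72 and -1.35 in P8 MG and -0.24, -3.12 and -2.35 in adult MG. The median of ratios gave -1.56 for miR-25 in P8 MG and 0.021, -2.86 and -2.09 in adult MG.

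With the highest negative control as background 45 miRNAs were higher in P8 MG against P2 RPC. Subtracting background gave 40 lower there and 9 higher in P11 MG against P8 MG. With no background threshold, which counts probes at background by construction, the numbers were 145 higher and 33 lower in P8 MG against P2 RPC, 11 and 17 in P11 MG against P8 MG, 48 lower in adult MG against P11 MG, 81 higher in adult MG against P2 RPC, and 46 ordered up and 68 down. A 1.5-fold threshold gave by construction more calls, 45 and 37, 18 and 17, 38 and 37, and 77 higher in adult MG against P2 RPC, with 40 ordered up. A 3-fold threshold gave fewer, 13 and 10, 1 and 3, 9 and 11, and 30 and 25, with 17 ordered down. The authors' scores, where probes at the floor of 1 give large ratios, gave 16 and 139 in P8 MG against P2 RPC, 31 and 22 in P11 MG against P8 MG, 77 higher in adult MG against P11 MG, 110 lower in adult MG against P2 RPC, 49 ordered up and 17 down, and -0.63, -1.99 and -1.65 for let-7, miR-25 and miR-124 in P8 MG. In all, 105 alternative values of these results moved and 143 did not; of the values for lists and named miRNAs 959 stayed and 1233 moved, and 3 more were list medians of at least 1 in size that changed sign; smaller medians that changed sign are not among these 3. In the authors' scores the miR-200 median in P8 MG against P2 RPC was -3.81, against 1.09 by the main rule, where 2 of the 3 members were upper bounds with P8 MG at background and so had no direction to reverse. The mural and mesenchymal median was -0.095 there, against 1.49, of which 1 of 2 members was a bound. The latter median was -0.47 in adult MG against P11 MG with the highest negative control as background, against 1.18. Causes were not tested.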

Other observations

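The tests of spill-over from miR-204, of lane background and of glial age for the probes numbered miR-1894 to miR-1983, the tests of scaling and immune-cell RNA for the microglia list, and the counting limits and P8 MG to P2 RPC ratios used to set background or scaling apart by probe were chosen only after the result was seen. The miRNAs of the next paragraph were also picked after their values were known.

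The mouse genome carries 3 similar clusters that join a miR-99 or miR-100 gene, a let-7 gene and a miR-125 gene. In adult MG against P2 RPC the log2 ratios of the probes that belong to 1 gene each were 3.99 for miR-99a, 6.16 for miR-100, -1.08 for miR-99b, 0.05 for let-7e and -0.65 for miR-125a-5p. The probes for let-7c (2.04), let-7a (-0.08) and miR-125b-5p (4.73) each read 2 genes in different places, so these values cannot be assigned to 1 cluster. The call of miR-99b as lower was lost under 3 of the 8 scalings.

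Among probes numbered miR-1894 to miR-1983, 13 of 21 above background were at least 2-fold higher in adult MG than in P2 RPC (61.9%) and 1 was lower, against 37 of 221 other miRNAs higher (16.7%). Lane background is argued against for 7 of the 13, whose raw adult MG to P2 RPC ratios had lower counting limits of at least 2.54, above the highest ratio among 41 negative and viral probes, 2.39. For the other 6, with ratios up to 2.76, the ratio cannot decide, since the background probes compared have few counts. These 6 calls were also lost under at least 1 scaling. In raw counts miR-1900 had 232 in P2 RPC and 455 in adult MG, miR-1896 172 and 308, and miR-1961 160 and 258. Negative controls reached at most 53 and 62, so background of that size is argued against for these. For miR-1955, miR-1959 and miR-1981 background cannot be told apart. A candidate explanation is spill-over from the miR-204 probe, which held 35.6% of adult counts. With a line on miR-204 through P2 RPC and adult MG, the P8 MG and P11 MG counts of the 13 deviated by a median of 0.145 (log2). For the 36 other higher miRNAs the median was 0.471. A small deviation was neither shared by all 13 nor particular to them. Of the 13, miR-1959 deviated by 0.448, while among the 36 others miR-181a deviated by 0.058 and miR-504 by 0.162. Among the 13, 8 stood above background in all 3 glial libraries. Of these, 6 ran in age order under the scaling used and the 8 other scalings, as miR-204 does. A true difference with age can therefore not be told apart from spill-over.

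All 4 microglia and white blood cell miRNAs above background were higher in P8 MG than in P2 RPC under the scaling used. The P8 MG lane had the highest background, but 2 of the 4, miR-146a with a raw ratio of 7.27 and miR-142-3p with 6.24, exceeded the highest ratio among 41 negative and viral probes, 3.50, with lower counting limits of at least 4.49. miR-150 (3.46) and miR-142-5p (2.01) did not, so the ratio leaves background open for these. In raw counts miR-142-5p had 157 in P2 RPC and 315 in P8 MG, while negative controls reached at most 53 and 114. Scaling of the P8 lane is argued against for miR-146a, with a lower counting limit of at least 2.56-fold under all 8 scalings. For the other 3 an excess over 2-fold cannot be told apart from scaling. Of these 3, only miR-142-3p kept its call under all 8. Its lower counting limit of 1.63-fold stayed above equality but under 2-fold. RNA from microglia carried through the sort is a candidate explanation that cannot be told apart from expression in glia. In P8 MG 4 of 6 listed miRNAs were above background, and miR-223, with 66 counts, was not. The last of the 6, miR-155, had 1 count in each of the 4 libraries, below all negative controls. Its count therefore cannot speak for or against immune-cell RNA.

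The P8 MG library had 5 probes above background whose normalized counts were at least 1.5-fold those of all 3 other libraries, miR-1940, miR-2140, miR-2141, miR-764-5p and miR-804, but with P11 MG counts at background set to the threshold miR-1940 (1.15-fold) and miR-764-5p (1.29-fold) were not. Against P2 RPC, lane background is argued against for miR-2141 and miR-804, whose raw ratios of 5.06 and 4.74 had lower counting limits of at least 3.55, above the highest among 41 negative and viral probes, 3.50. By ratio it stays open for the other 3, with ratios up to 3.33, and for the excess of all 5 over P11 MG, where 0 of the 5 exceeded the highest background ratio, 2.77, and miR-2141 came closest at 2.75. In raw counts miR-2141 had 1088 in P8 MG and 396 in P11 MG, while negative controls reached at most 114 and 97. Background of that size is argued against for the excess of miR-2141 over P11 MG. Scaling of the P8 lane is argued against for miR-2141, whose ratio to each other library had a lower counting limit of at least 1.79 under all 8 scalings. For the remaining 4 it cannot be told apart, since of these only miR-804 kept the 1.5-fold excess under all 8. Its lower counting limit of 1.45 stayed above equality but under 1.5. No biological explanation was tested.

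A hypothesis written before its test was that miRNAs from neighbouring genes, which may share a precursor transcript, differ alike between P2 RPC and adult MG. Over 73 pairs of miRNAs in 29 clusters the median difference between the log2 ratios of neighbours was 0.74, against 1.53 for random pairs, and 1 of 10000 random draws was as small. The matching of probe names to genes was widened after a first look at the result, which had covered 34 pairs (0.76, percentile 2.93). The difference also held for 55 pairs from different families (0.74, percentile 0.37), for 46 pairs without the Dlk1-Dio3 cluster (0.81, percentile 0.33), and with both restrictions for 28 pairs (0.81, percentile 1.49). Probes of 1 family can cross-hybridise, which the pairs from different families address only in part.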
